A study of Mus musculus with 4 samples.

How the data were processed

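Total RNA from mouse bone marrow-derived dendritic cells was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of it for Affymetrix arrays, per the labels' protocols. There were 4 arrays, 2 from cells given diluent and 2 from cells given SAHA for 12 hours. The groups and replicate numbers were taken from the sample titles. The authors deposited 1 table of log2 values per probe set. That the values are on a log2 scale was read from the values themselves, which lay between 2.59 and 15.0 with array medians of 5.34 to 5.35. R 2.7 is named in the submitters' processing notes, and the method by which probes were summarised and arrays normalized is not given in the sources used here. The medians lay within 0.0118 of each other, so the deposited normalization was kept. Arrays give no read depth, and the number of arrays limits the precision.

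The array held 45101 probe sets, of which 34958 were paired with 1 gene symbol, 932 with several and 9211 with none, in the platform annotation used, which can be old. Of the array's 64 control probe sets 13 carried 1 symbol and were kept as probe sets of Actb, Gapdh, Pcx and Tfrc. Symbols were updated through the Entrez identifier, which a RefSeq gene table held for 34754 of the 34958 probe sets, and the symbol of the platform annotation was kept otherwise. Each gene was read by the probe set with the highest mean over the 4 arrays among those with 1 symbol, which gave 18194 genes. Of 553 symbols on the fixed gene lists 504 were measured, and the rest were not analysed here.

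Control and SAHA arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, on the deposited log2 values, with no intensity filter and no covariate. The Benjamini-Hochberg adjusted p had to be under 0.05. Fold changes are ratios of the values after undoing the log2, and an SE is the moderated standard error of the log2 change. Where a value of a named gene lay under the 25th percentile of its array, that percentile took its place and the fold or change is given as a bound or beside the measured one, a choice made after the values were seen. The 33 gene lists, of pathways and of cell type markers, were tested with limma's camera, which compares the members with all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 33 lists. Camera with an estimated correlation and fry, which tests whether the members move on balance one way, were alternatives. Counts of members past the threshold are given over all genes and adjusted over the list alone.

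The gene lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls among genes past the threshold, with both SAHA arrays on the same side of both control arrays and a mean over the 4 arrays above the median of genes. It added 20 genes fixed by name, and for each list the 2 to 4 members with the largest change among those past the threshold, or among all members where none passed. Genes named outside it are said to have been named after their values were seen.

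The gene test was tested on simulated arrays with the real genes' means and spreads and 200 changed genes in each of 5 draws over 18194 genes. It called 27% of genes changed 2-fold and 72.4% of genes changed 4-fold, and 3.12% of its calls were false. A shifted list, with every member moved 2-fold, was called in 5 of 5 draws, and an unshifted list in 0. That shift was larger than the median change of any real list that passed, so it gives no rate for smaller or mixed shifts. The simulated genes varied independently of each other and of replicate number, so these rates may be too favourable for real, correlated genes.

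Alternatives were eBayes without the trend and with robust spread, quantile normalization, median centring, a floor at the 20th percentile of values, an offset of 32 on the linear scale, genes above the median level alone, the mean of a gene's probe sets, each probe set on its own, a threshold of 0.01, replicate number as a term in the design, an ordinary linear model, and fits without each array in turn. In the last the lone array of a group is assumed to vary like the other group. RefSeq coordinates were not used, since no build is named for the values. Probe sets with several symbols or none entered no gene result and were tested apart, without the control probe sets.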

Results

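Gene expression was measured on 4 Affymetrix arrays in dendritic cells grown from the bone marrow of C57BL/6 mice, 2 treated with diluent (control) and 2 with SAHA. SAHA (vorinostat) is a hydroxamic acid that inhibits histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. Dendritic cells take up antigen and present it to T cells. The marrow came from at least 3 mice per experiment and was cultured for 7 days with GM-CSF and IL-4, each at 10 ng/ml. Cells carrying CD11c, an integrin chain used to select dendritic cells, were then isolated to a stated purity of 95% and treated for 12 hours. The SAHA dose is written as 500 nm in the labels. The question was how SAHA changed the overall expression profile of these cells. The labels call the arrays biological replicates without saying whether each came from a separate marrow pool, so the p-values measure the spread between these arrays. With 2 arrays per group an exact two-sided permutation test of 1 gene could not go below p = 0.333, and the small number of arrays limits the precision of every value. Across 18194 genes the control arrays correlated at 0.993 with each other and the SAHA arrays at 0.995, and arrays of different groups correlated at 0.983 to 0.989 (Pearson's r across genes, which are not independent replicates). The log2 difference between the 3' and 5' probe sets of beta-actin, a sign of RNA quality, was 0.19 ± 0.05 (SD, n = 2) in control and 0.25 ± 0.02 (SD, n = 2) in SAHA-treated cells. For Gapdh it was -0.16 ± 0.07 and -0.07 ± 0.09, for pyruvate carboxylase 1.05 ± 0.43 and 1.35 ± 0.23, and for the transferrin receptor 1.37 ± 0.46 and 1.04 ± 0.18, and each of these differences was within the larger range of the arrays of a group.

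With SAHA, H2-Ob, the beta chain of the MHC class II accessory molecule H2-O, rose from 3.79 ± 0.20 to 8.31 ± 0.26 log2 units (SD, n = 2 per group). Its control values lay under the 25th percentile of their arrays, and with that percentile in place of them the rise was at least 19.7-fold. Prtn3, the neutrophil granule protease proteinase 3, rose 12.6-fold, from 5.41 ± 0.43 to 9.07 ± 0.21 log2 units. Lyl1, a helix-loop-helix transcription factor of blood progenitors, rose 8.01-fold, from 6.35 ± 0.09 to 9.35 ± 0.02 log2 units. In the other direction 2610528A11Rik, which encodes the GPR15 ligand GPR15L, fell 9.37-fold, from 8.61 ± 0.12 to 5.39 ± 0.02 log2 units. In total 405 of 18194 genes differed between the groups (limma, Benjamini-Hochberg adjusted p under 0.05), with 276 higher and 129 lower in SAHA-treated cells. Of these, 204 of the higher and 83 of the lower genes changed at least 2-fold. The count was 31 genes without SAHA replicate 1 and 90 without SAHA replicate 2, against 529 without control replicate 1 and 347 without control replicate 2. No gene passed in an ordinary linear model without moderation (2210 at an unadjusted p under 0.05) or after a floor at the 20th percentile of values (3034), against 3287 in limma without either change. The ordinary model takes each gene's spread from 2 arrays per group alone, so it had little power over 18194 genes.

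**Figure D1:**
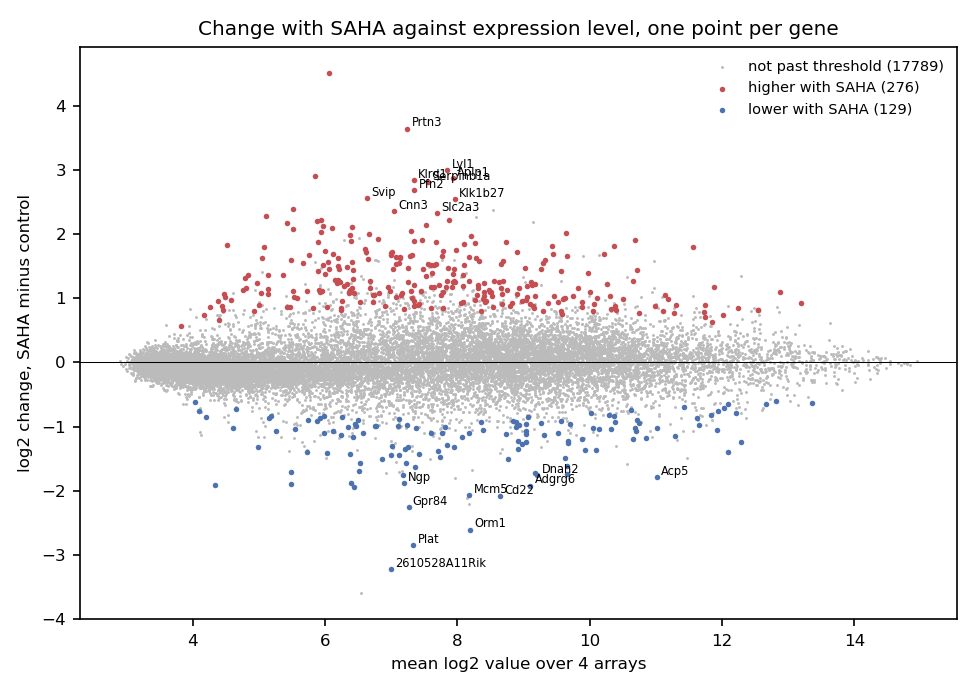
Log2 change with SAHA (SAHA minus control, means of 2 arrays each) against the mean log2 value over 4 arrays, with one point per gene and the 276 higher and 129 lower genes coloured. The 10 largest rises and 10 largest falls among genes past the threshold and above the median level are named, and the uppermost unnamed point is H2-Ob, whose control values lay under the 25th percentile of their arrays.

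Among genes past the threshold with a mean above the median of all genes, the 10 largest rises spanned 5.06-fold to 12.6-fold. After Prtn3 and Lyl1 came Aplp1, an amyloid precursor-like protein mostly known from neurons, at 7.40-fold (log2 change 2.89 ± 0.19, SE, adjusted p = 0.00833). Klrd1, the CD94 chain of NK cell receptors, rose 7.18-fold (2.84 ± 0.33, adjusted p = 0.0180). Serpinb1a, an inhibitor of neutrophil serine proteases, rose 7.03-fold (2.81 ± 0.19, adjusted p = 0.00833). The actin-binding proteins Pfn2, a profilin, and Cnn3, a calponin, rose 6.47-fold and 5.17-fold. Svip, a small protein that binds the ATPase VCP, rose 5.91-fold, the kallikrein-family protease Klk1b27 rose 5.85-fold, and the glucose transporter Slc2a3 rose 5.06-fold. All 10 passed the threshold without each array in turn, and 9 passed when all probe sets of a gene were averaged, the exception being Pfn2 (1.76 on the log2 scale). The probe sets reporting Aplp1, Cnn3 and Slc2a3 are of types that can share sequence with other transcripts, and their further probe sets with every value above the 25th percentile of its array, 1 for each gene, gave log2 changes of 1.45, 1.55 and 2.09. Such further probe sets gave 1.08 for Svip and 0.77 and 1.81 for Pfn2.

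The 10 largest falls under the same rule spanned 3.40-fold to 9.37-fold. Plat, tissue plasminogen activator, was 7.23-fold lower (log2 change -2.85 ± 0.47, SE, adjusted p = 0.0407), and Orm1, the acute-phase protein orosomucoid, was 6.10-fold lower (-2.61 ± 0.34, adjusted p = 0.0240). Gpr84, a receptor for medium-chain fatty acids on myeloid cells, was 4.78-fold lower (-2.26 ± 0.19, adjusted p = 0.0111). Cd22, an inhibitory receptor best known from B cells, was 4.26-fold lower, and its second probe set gave -2.56 on the log2 scale. Mcm5, a subunit of the replicative helicase, was 4.18-fold lower, and the adhesion receptor Adgrg6 3.79-fold lower. Both were read by probe sets of types that can share sequence with other transcripts, and a further probe set gave -1.995 for Mcm5 and -1.02 for Adgrg6. Ngp, a neutrophil granule protein on a marker list with a median of -0.68, Ngp included, was 3.68-fold lower, Acp5, the tartrate-resistant acid phosphatase of macrophages and osteoclasts, 3.44-fold lower, and Dnah2, an axonemal dynein chain, 3.40-fold lower. Of these 10, 2610528A11Rik, Gpr84 and Acp5 passed without each array in turn, and the other 7 lost the threshold without SAHA replicate 1, with an adjusted p of 0.172 for Plat, 0.114 for Orm1, 0.0877 for Cd22 and Mcm5, 0.0972 for Adgrg6, 0.0593 for Ngp and 0.172 for Dnah2. Plat, Mcm5 and Dnah2 also missed it when probe sets were averaged, at -1.70, -1.45 and -1.01 on the log2 scale, where Plat has a further probe set at -0.55 and the means of Mcm5 and Dnah2 include 1 with values under the 25th percentile. These 3 and Adgrg6 missed it among genes above the median level, at an adjusted p of 0.0522 to 0.0596 with their changes unmoved. Plat also missed it without the intensity trend (0.0502), with robust spread (0.0653) and with an offset of 32 on the linear scale (0.0565), and Dnah2 without the trend (0.0520) and with that offset (0.0511).

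**Figure D2:**
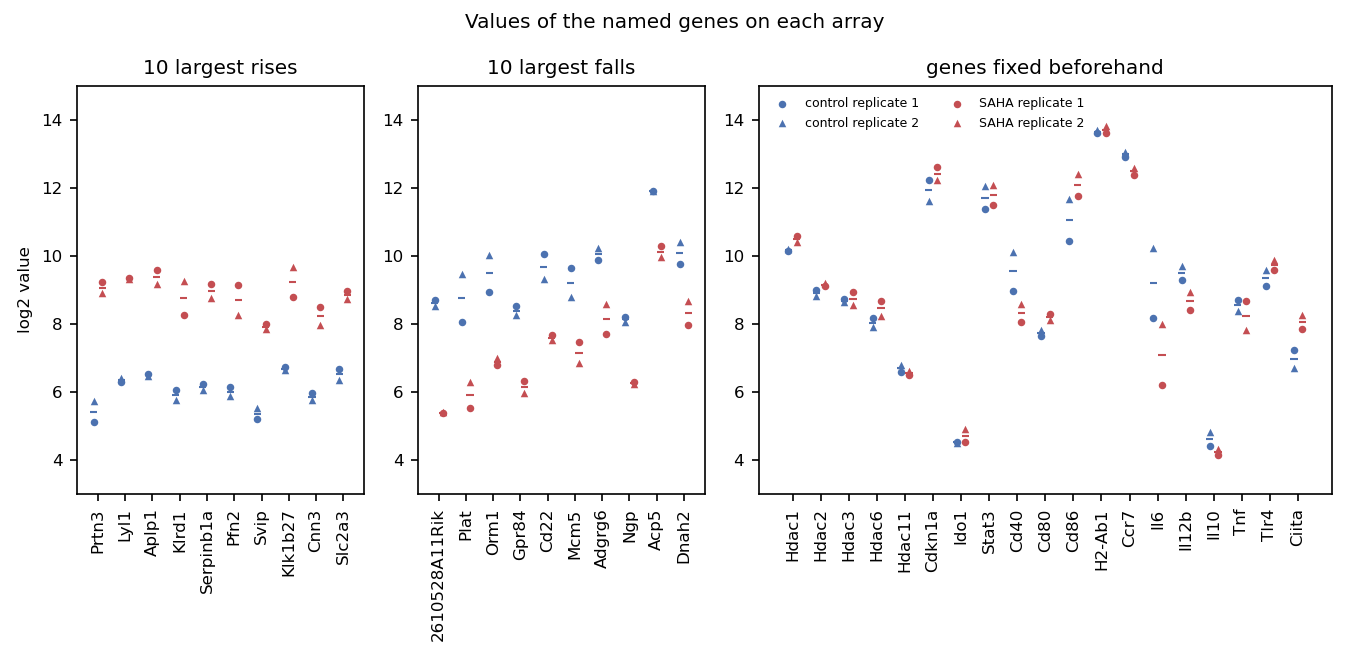
Log2 value on each array for the 10 largest rises, the 10 largest falls and the genes fixed beforehand, with control in blue, SAHA in red, circles for replicate 1, triangles for replicate 2 and bars for group means. The rule for the 20 genes with the largest changes required both SAHA arrays on the same side of both control arrays, and Il6, which did not pass, lies at 8.16 and 10.24 in control and at 6.19 and 7.99 in SAHA-treated cells.

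Several genes of interest for this drug and cell type had been fixed before the data were examined. None of the 19 analysed here passed the threshold over all genes in the main fit, which has no term for replicate number. With that term 69 of all the named genes that had not passed did so. It was not used for calls, since no label ties the numbers to shared cultures. Among inflammatory genes, Il6 had a log2 change of -2.11 ± 0.78 (SE, adjusted p = 0.232), Il12b, the shared subunit of IL-12 and IL-23, -0.84 ± 0.23 (0.130), Tnf -0.31 ± 0.29 (0.614) and Il10 -0.38 ± 0.17 (0.303). The costimulatory genes went both ways, with Cd40 at -1.21 ± 0.38 (0.169), Cd80 at 0.47 ± 0.16 (0.206) and Cd86 at 1.04 ± 0.40 (0.248). Ccr7, the receptor that guides dendritic cells to lymph nodes, had a change of -0.49 ± 0.13 (0.118). Ido1, which breaks down tryptophan, lay near the bottom of the scale at 4.52 ± 0.02 in control and 4.71 ± 0.26 in SAHA-treated cells (SD, n = 2 per group). Stat3 had a change of 0.08 ± 0.28 (0.908), Tlr4 of 0.37 ± 0.20 (0.393) and the cell cycle inhibitor Cdkn1a of 0.49 ± 0.23 (0.334). The deacetylase genes fixed by name ranged from -0.13 for Hdac11 to 0.42 for Hdac6, with 0.32 for Hdac1, 0.25 for Hdac2 and 0.05 for Hdac3. Ciita, the master regulator of MHC class II genes, had a change of 1.09 ± 0.23 (0.0759), and H2-Ab1, a class II beta chain, of 0.06 ± 0.12 (0.819). The histone gene H1f0 was not analysed here.

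Gene lists fixed beforehand were each tested against all other genes, and 4 of the 33 lists passed (limma camera with a preset inter-gene correlation of 0.01, adjusted p under 0.05), 2 higher and 2 lower. None of the 33 passed with an estimated correlation, where each of these 4 had an adjusted p of 0.918. With 2 arrays per group that variant has few residual degrees of freedom and little power. Calls lost under it therefore do not show that the members of a list are correlated. Of the 37 genes past the threshold that the naming rule took, 22 lost it without SAHA replicate 1, 19 without SAHA replicate 2, 5 without control replicate 1 and 6 without control replicate 2, and among those named as list members only, H2-Ob and Cd28 kept it in each of these fits. The list named replication-independent and variant histones passed on the higher side, with a median log2 change of 0.51 (adjusted p = 0.000613). Genes of the histone clusters, H2bc21 among them, were also on it, so the name does not hold for every member. The call was lost with an estimated correlation (adjusted p = 0.918) and with fry (adjusted p = 0.118). Of 11 measured members 2 were below 0, 3 were higher over all genes, none was lower, and 6 were higher when adjusted over the list alone. H3f3b, a histone H3.3 gene, rose 2.75-fold (log2 change 1.46 ± 0.17, SE, adjusted p = 0.0177), H2bc21 rose 2.01-fold and H2aj 1.99-fold. H3f3b was read by 1 probe set, at 7.21 log2 units in control, and H2aj had a change of 0.45 when its probe sets were averaged and then missed the threshold. H2bc21, read by a probe set of a type that can share sequence, with a further one at 0.90, missed it then too (adjusted p = 0.0560), and with quantile normalization (0.0742), the offset of 32 (0.0637) or genes above the median level alone (0.0543). No histone deacetylase gene passed among 11 measured, over all genes or adjusted over the list alone, and that list had a median of 0.05 (adjusted p = 0.582). Hdac7 had a change of -0.31. Among 22 other chromatin modifiers Kdm5b, a histone lysine demethylase, rose 3.35-fold, with further probe sets at 0.72 and 0.78 on the log2 scale, and none fell over all genes, while 1 was higher and 1 lower when adjusted over the list alone, the latter being Crebbp at -0.76, named after its value was seen. That list did not pass (median 0.07, adjusted p = 0.580).

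Cell cycle and DNA replication genes passed as a list on the lower side, with 20 of 24 measured members below 0 and a median log2 change of -0.56 (camera, adjusted p = 0.00224). The call was lost with an estimated correlation (adjusted p = 0.918), with fry (0.812), with the floor at the 20th percentile (0.0863) and among genes above the median level (0.0727). Mcm5 was the 1 member that fell over all genes, and none rose. When adjusted over the list alone 5 members were lower and 1 was higher. These were Mcm5, the helicase subunit Mcm4 (-0.91), the ribonucleotide reductase subunit Rrm2 (-1.70), thymidylate synthase Tyms (-0.46) and the replication licensing factor Cdc6 (-1.16) on the lower side and Pcna, the sliding clamp, at 0.35, of which all but Mcm5 were named after their values were seen. The size of this shift depended on control replicate 1, since without it the median was -0.20, and without SAHA replicate 2 it was -0.42. The call was lost in both fits, which also set unlike replicate numbers against each other. Between same-numbered arrays Mcm5 went from 9.64 to 7.46 in replicate 1 and from 8.78 to 6.83 in replicate 2. Mcm2, Mcm3, Mcm4 and Mcm7 were likewise lower with SAHA in both replicates, and Mcm6 in replicate 1 only. Over all 4 arrays the neutrophil markers had a median of -0.68. Among 10 CDK inhibitors and GADD45 genes Cdkn2d, an INK4-type inhibitor, rose 2.05-fold and none fell, with 2 higher and 2 lower when adjusted over the list alone (list median -0.01, adjusted p = 0.734). In the BCL2 family of cell death regulators Bid rose 1.85-fold among 14 measured members and none fell, with 2 higher and 1 lower when adjusted over the list alone (list median 0.25, adjusted p = 0.117). Bid lost its call when its probe sets were averaged (0.64, adjusted p = 0.0913).

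MHC class II presentation genes passed as a list on the higher side (camera, adjusted p = 0.0158), with a median log2 change of 0.09 but a mean of 0.69, or 0.67 with H2-Ob at its bound. The call was lost with an estimated correlation (adjusted p = 0.918), with fry (0.179), with the floor at the 20th percentile (0.0863), without SAHA replicate 2 (adjusted p = 0.0630) and among genes above the median level (adjusted p = 0.489), a set that leaves out H2-Ob. Of 11 measured members H2-Ob rose and Ifi30, a lysosomal thiol reductase, fell 1.55-fold over all genes, and 5 were higher and 1 lower when adjusted over the list alone. Ifi30, with 1 probe set, stayed at -0.63 but lost its call without the intensity trend (adjusted p = 0.0718), with the offset of 32 (0.0540) and when the probe sets of other genes were averaged (0.0637). The 5 higher ones were H2-Ob, its partner chain H2-Oa (1.21), Ciita, and the peptide-loading chains H2-DMb2 (0.73) and H2-DMa (0.59), of which H2-Oa, H2-DMb2 and H2-DMa were named after their values were seen. H2-O is known to restrain the peptide loading that H2-DM catalyses. MHC class I presentation genes did not pass as a list (15 measured, median -0.03, adjusted p = 0.734), and no member passed over all genes. The immunoproteasome subunit Psmb10 had a change of -1.50 (adjusted p = 0.0583) and was the 1 member lower when adjusted over the list alone, with Erap1 at -0.50, Tap2 at 0.47 and Nlrc5 at 0.44.

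Costimulation and maturation genes of dendritic cells did not pass as a list (18 measured, median -0.28, adjusted p = 0.523). Cd200, the ligand of an inhibitory receptor, fell 2.14-fold (log2 change -1.10 ± 0.17, SE, adjusted p = 0.0361) and none rose over all genes. When adjusted over the list alone 8 members were lower, among them Cd40 and Ccr7, and 3 were higher, namely Cd80, Icosl (1.05) and Tnfsf9 (0.81), the last pair named after their values were seen. Inhibitory and tolerance-associated genes did not pass (16 measured, median 0.04, adjusted p = 0.953), and no member did so over all genes. The arginase gene Arg1 had a value of -3.60 ± 0.90 (adjusted p = 0.111), or -3.51 with SAHA replicate 1, which lay under the 25th percentile of its array, put at that percentile. Other values were Ahr at 0.67, Socs1 at -0.66 and Arg2 at 0.50, and 1 member was higher and 1 lower when adjusted over the list alone. Of 17 proinflammatory cytokines Il18 rose 2.24-fold and none fell (list median -0.27, adjusted p = 0.580), with 1 higher and none lower when adjusted over the list alone. Il18, with 1 probe set, lost its call with quantile normalization (1.11, adjusted p = 0.0551) and, with its change unmoved at 1.16, among genes above the median level (0.0522) and when the probe sets of other genes were averaged (0.0503). No chemokine passed among 20 measured (list median 0.05, adjusted p = 0.582), with Ppbp at 0.81, Ccl3 at 0.79, Cxcl16 at -0.66 and Cxcl2 at 0.64.

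No chemokine receptor or integrin passed over all genes among 15 measured (list median -0.12, adjusted p = 0.783), whereas 3 were higher and 2 lower when adjusted over the list alone. Ccr2, the receptor for the monocyte chemokine CCL2, had a change of 1.58, Itgb7 of 1.05, Cx3cr1 of -0.49 and Cxcr4 of -0.46. Type I interferon-stimulated genes had no member past the threshold in either adjustment (20 measured, median -0.003, adjusted p = 0.734), with Cmpk2 at 1.02 ± 0.88, Ifit1 at 0.79, Irf7 at -0.71 and Rsad2 at 0.62. The toll-like receptors and their adaptors had none either (20 measured, median -0.17, adjusted p = 0.582), with Tlr1 at -1.11, Tirap at -0.62, Tlr2 at 0.55 and Tlr6 at -0.55. Among 20 Fc receptors, scavenger receptors and C-type lectins, Clec10a, a galactose-binding lectin, rose 3.65-fold and Clec4e, the glycolipid receptor Mincle, rose 1.91-fold. None fell over all genes, 2 were higher and 2 lower when adjusted over the list alone, and the list had a median of -0.12 (adjusted p = 0.705). Of 18 lysosomal genes the collagen-degrading cathepsin Ctsk fell 2.28-fold and none rose (list median -0.0047, adjusted p = 0.818), and 1 was lower when adjusted over the list alone. Ctsk, with 1 probe set, stayed at -1.19 but lost its call among genes above the median level (adjusted p = 0.0532) and when the probe sets of other genes were averaged (0.0509).

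Metabolic and stress-response lists did not pass, and none of their members passed over all genes. For cholesterol biosynthesis (19 measured) the median was -0.07 (adjusted p = 0.705), with 2 members lower when adjusted over the list alone and Pmvk at -1.002, Insig1 at -0.82, Fdps at 0.81 and Fdft1 at 0.72. For cholesterol efflux and lipid storage (14 measured) it was -0.11 (adjusted p = 0.734), with Nr1h3 at -0.98, Apoe at -0.69 and Scd2 at 0.54. Glycolysis (14 measured) had a median of -0.02 (adjusted p = 0.754) and its members Pfkfb3 and Hk3 had changes of -1.32 and -0.55, with Hk1 at 0.52 and Pfkp at 0.51. Oxidative phosphorylation (19 measured) had a median of -0.04 (adjusted p = 0.778), with Sdhb at -0.48, Uqcrc1 at -0.42 and Ndufv1 at 0.33, and ribosomal proteins (13 measured) had a median of 0.00037 (adjusted p = 0.523), with Rps18 at 0.26 and Rps14 at 0.21. NRF2 targets and metallothioneins (11 measured) had a median of -0.22 (adjusted p = 0.580), with Nqo1 at -0.68 and Mt2 at 0.59. The unfolded protein and heat shock list (16 measured) had a median of -0.22 (adjusted p = 0.117), with 2 members lower when adjusted over the list alone and the chaperone genes Hspa5 at -0.56 and Hsp90b1 at -0.50. Neuronal genes (18 measured) had a median of -0.04 (adjusted p = 0.734), with 1 member higher when adjusted over the list alone, the synaptic vesicle gene Syn1 at 1.00 (adjusted p = 0.0503 over all genes).

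**Figure D3:**
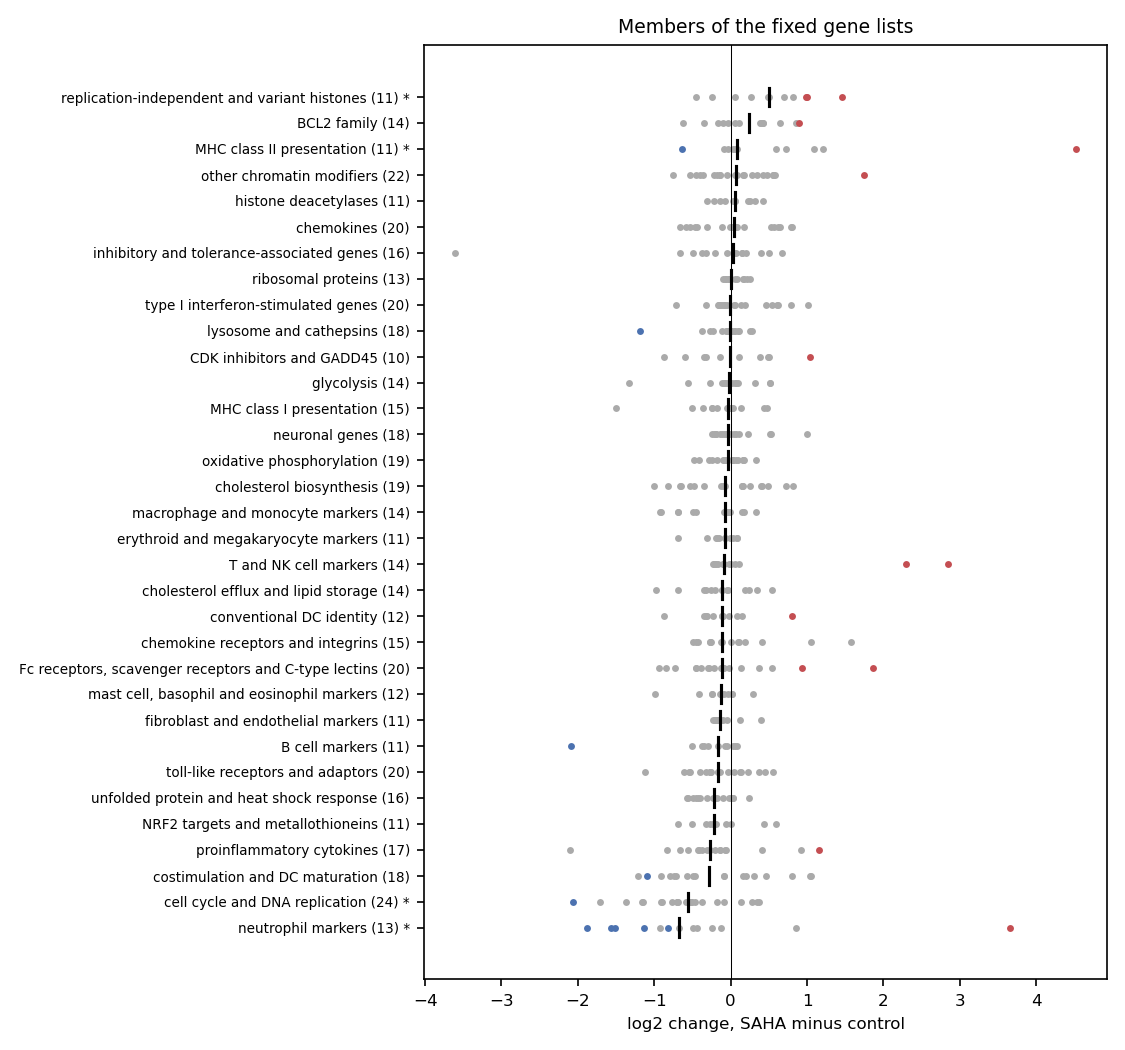
Log2 change with SAHA of each measured member of the 33 gene lists, with the number measured in parentheses, black bars at list medians, red and blue points for members higher or lower over all genes and an asterisk where the list passed in camera. The lists run from a median of -0.68 for neutrophil markers to 0.51 for variant histones.

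Markers of neutrophils, cells that share the bone marrow with dendritic cell precursors, passed as a list on the lower side (13 measured, median log2 change -0.68, camera adjusted p = 0.00224, and adjusted p = 0.918 with an estimated correlation). Over all genes 5 fell and 1 rose, and 8 were lower and 2 higher when adjusted over the list alone. The granule proteins Ngp, Ltf (-1.56 ± 0.20, SE), and Camp (-1.13 ± 0.18) and the calprotectin chains S100a9 (-1.51 ± 0.16) and S100a8 (-0.82 ± 0.13) fell, whereas Prtn3 rose. Camp and S100a8 were named after their values were seen. The call was lost among genes above the median level (adjusted p = 0.0534). Conventional dendritic cell identity genes did not pass as a list (12 measured, median -0.11, adjusted p = 0.734), and Irf4, a transcription factor of one dendritic cell branch, rose 1.75-fold, none fell over all genes, and 1 was higher and 1 lower when adjusted over the list alone. Irf4 lost its call when its probe sets were averaged (0.53, adjusted p = 0.215), the second one giving 0.26, and among genes above the median level, its change unmoved (adjusted p = 0.0532). Macrophage and monocyte markers did not pass (14 measured, median -0.08, adjusted p = 0.298), and none of them did over all genes, with 2 lower when adjusted over the list alone. Their values included Maf at -0.93, Mertk at -0.92 (adjusted p = 0.0509) and Trem2 at -0.69 (adjusted p = 0.0553).

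Lymphoid markers did not pass as lists. Of 14 T and NK cell markers Klrd1 and Cd28, a costimulatory receptor of T cells, rose 7.18-fold and at least 4.39-fold, the latter a bound because a control value lay under the 25th percentile of its array. The other 12 did not pass, and both adjustments gave 2 higher and none lower. The list had a median of -0.09 and a mean of 0.28, or 0.27 with Cd28 at its bound (adjusted p = 0.734). Of 11 B cell markers Cd22 fell and none rose, and 2 were lower when adjusted over the list alone (median -0.16, adjusted p = 0.117). No erythroid or megakaryocyte marker passed over all genes (11 measured, median -0.08, adjusted p = 0.580), with Car2 at -0.69 and 1 lower when adjusted over the list alone. No mast cell, basophil or eosinophil marker did in either adjustment (12 measured, median -0.13, adjusted p = 0.298), with Prg2 at -0.99 and Siglecf at 0.30. No fibroblast or endothelial marker did either (11 measured, median -0.14, adjusted p = 0.612), with Vwf at 0.40 and Cdh5 at -0.23.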

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

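Probe sets outside the gene comparison also responded. Among the 10092 probe sets with several gene symbols or with none, control probe sets left out, 13 were higher and 3 lower with SAHA when each probe set of the array was tested on its own (limma, adjusted p under 0.05). The 13 were above the control arrays in data that no gene result used, and at 0.129% were a smaller share than the 170 higher among the 34958 probe sets with 1 symbol (0.486%). The largest rise was in probe set 1438183_x_at, with a log2 change of 2.02 ± 0.17 (SE, adjusted p = 0.0269), from 5.19 and 4.91 in control to 7.10 and 7.03 in SAHA-treated cells. It was followed by probe set 1426584_a_at, at 1.84 ± 0.24 (adjusted p = 0.0407). Their genes are unnamed here, and no explanation was tested.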

How the results depend on the processing

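All alternatives reported in this part had been chosen before the data were examined. The 405 genes past the threshold numbered 402 to 448 with no intensity trend, robust spread or quantile normalization, and 385 after median centring. Quantile normalization gave 254 higher and 148 lower genes, 63.2% higher against 68.1%. With an offset of 32 there were 316 genes, 178 of them changed at least 2-fold against 287. With genes above the median level alone there were 226, 154 higher, 72 lower and 165 at least 2-fold, which follows in part from the fewer genes tested, as 291 of the 405 lay in that set and 224 of these were called again. The mean of all probe sets of a gene gave 274, 84 of them lower and 185 at least 2-fold. Each of the 45101 probe sets on its own gave 241, with 183 higher and 58 lower. At a threshold of 0.01 there were 8 genes, 7 higher, 1 lower and 8 at least 2-fold. The ordinary linear model and the floor gave 0 genes higher, 0 lower and 0 at least 2-fold, with 2210 and 3034 genes at an unadjusted p under 0.05 against 3287 in limma. The ordinary model has little power with 2 arrays per group. Floored genes without any spread enter limma's pooled estimate, and the cause of the lost calls was not tested further.

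Without each array in turn there were 31 to 529 genes past the threshold, 25 to 362 higher, 6 to 167 lower and 31 to 444 at least 2-fold. The lowest counts came without SAHA replicate 1 (31, all among the 405) and SAHA replicate 2 (90, of which 79 were among them), and the highest without control replicate 1 (529, of which 311 were). Without control replicate 2 there were 347, of which 236 were. These fits have 3 arrays. Of the 37 named genes past the threshold, 15 passed without each array in turn, 22 lost it at least once, and none changed sign under any alternative. Apart from the genes with the largest falls, H2aj, Bid and Pfn2 lost it with the mean of probe sets, and Il18, H2bc21, Ifi30, Ctsk and Irf4 with that and with 1 or more of the scaling, trend, offset and level alternatives, at an adjusted p of 0.0503 to 0.215. Il18, Ifi30 and Ctsk have 1 probe set, so their changes did not move when probe sets were averaged.

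The 4 gene lists past the threshold (2 higher, 2 lower) became 0 with an estimated inter-gene correlation (0 higher, 0 lower) and 1 with fry (0 higher, 1 lower, the neutrophil markers at adjusted p = 0.00961, range over its alternatives 0.000663 to 0.918). They became 1 (1 higher, 0 lower) with list members above the median level or with such genes alone, 2 with the floor (1 higher, 1 lower), and 2 to 7 without each array in turn (1 to 3 higher, 1 to 4 lower), with 7 without SAHA replicate 1, 6 without control replicate 2, 3 without control replicate 1 and 2 without SAHA replicate 2. The variant histone list kept its call in each of these fits but those with an estimated correlation (adjusted p = 0.918) and fry (0.118). The cell cycle and MHC class II calls were lost with the estimated correlation, fry, the floor and either restriction to genes above the median level, and the neutrophil call with the estimated correlation and both restrictions. The cause of these lost calls was not tested.

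Of the named genes that had not passed, 10 changed sign. Stat3 had a log2 change of -0.023 with the mean of its probe sets and -0.27 to 0.42 without each array in turn. In those fits Cmpk2 ran from -0.37 to 2.40, Apoe from -2.0 to 0.61, Uchl1 from -0.0017 to 1.03, Siglecf from -0.83 to 1.43, Vwf from -0.42 to 1.21, Hdac3 from -0.14 to 0.24, Mt1 from -0.021 to 0.90, H2-Ab1 from -0.053 to 0.17 and Tnf from -0.72 to 0.11. A fit without 1 array also sets unlike replicate numbers against each other. Between same-numbered arrays Stat3, Cmpk2, Uchl1 and Mt1 were higher with SAHA in both replicates, and Apoe and Tnf lower in both. Apoe, for example, went from 7.45 to 6.46 in replicate 1 and from 9.47 to 9.07 in replicate 2. Siglecf, Vwf, Hdac3 and H2-Ab1 went both ways. The cause was not tested further.

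The replicate numbers 1 and 2 recur in both groups, and the labels do not say that they mark a shared culture. Deviations of same-numbered arrays from their group means correlated at 0.567 across genes. With the replicate number as a block there were 3616 genes, 1954 higher, 1662 lower and 465 at least 2-fold, including all 405 and 69 of the named genes that had not passed, and 5 lists passed, 2 higher and 3 lower. The second principal component, the axis of largest variation between arrays after the first, held 27.8% of the variance. On it the replicate 1 arrays lay at 23.4 (control) and 8.53 (SAHA) and the replicate 2 arrays at -14.3 and -17.6. Same-numbered arrays thus shared a difference whose source is not labelled. With 2 pairs it cannot be told whether they were paired by design, and the blocked counts were not used. If they were paired, the main fit counted that difference as error.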

Other observations

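Of the tests in this part, the comparison with random genes of equal expression level was set before its result was seen, and all the others only after. Some genes of cilium transport rose. Families of at least 5 genes sharing a symbol stem, 558 in all, were tested with camera, and 3 passed, none of them with an estimated correlation (adjusted p = 0.993). That variant has little power with 2 arrays per group. The Ift genes, which encode the particles that carry cargo along cilia, had a median log2 change of 0.45 over 14 genes (adjusted p = 0.000103), with 13 above 0 and 4 past the threshold. Of these Ift81 rose 4.65-fold (2.22 ± 0.18, SE, adjusted p = 0.0108), Ift74, its binding partner, 3.30-fold, Ift122 2.18-fold and Ift27 2.00-fold. Ift81, Ift122 and Ift27 were read by probe sets of types that can share sequence with other transcripts, and their further probe sets with values above the 25th percentile gave 0.76 for Ift81, 0.89 for Ift122 and 0.17 and 0.76 for Ift27. The Bbs genes, whose products form and assemble a coat for ciliary membrane proteins, had a median of 0.77 over 8 genes, all above 0 (adjusted p = 0.000107), and 2 passed, Bbs12 at 2.10-fold and Bbs1 at no less than 1.72-fold. The other 16 genes did not pass, Ift172 among them at -0.40 and Ift43 and Ift52 at 0.10. The Mcm genes had a median of -0.62 over 10 genes (adjusted p = 0.0192), with an adjusted p of 0.215 without control replicate 1 and of 0.0797 without SAHA replicate 2. For Ift and Bbs the adjusted p ran from 5.45e-05 to 0.000464 without each array in turn.

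The 22 Ift and Bbs genes together had a median of 0.57, with 21 above 0. The tables argue against a general rise of dim genes, since the central 95% of 10000 random gene sets matched on mean expression ended at 0.13 and none reached 0.57. The families were picked by their change in the same arrays, so lying above random sets is no further support for their rise. They argue against cells with motile cilia among the SAHA-treated cells, since 25 markers of motile cilia had a median of -0.019 (95% interval -0.20 to 0.08), none passed, and the 16 with every value above the 25th percentile of its array had a median of -0.17 (-0.33 to 0.04). The intervals of the marker medians treat the markers as independent and give the spread between genes, not between replicate arrays. Markers read on the same arrays can vary together, so these intervals may be too narrow. Cells with primary cilia, which lack those markers, stay open and were not tested, nor was a response of the dendritic cells to SAHA.

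Cd28 rose at least 4.39-fold and Klrd1 7.18-fold in cells selected for CD11c. More T or NK cells would bring their other transcripts, but the other 12 markers had a median log2 change of -0.10 (95% interval -0.21 to 0.01), and the 9 with every value above the 25th percentile of its array had one of -0.10 (-0.21 to 0.05). These intervals, too, run over genes treated as independent and not over replicate arrays. Zap70, the brightest of these markers, went from 8.90 to 8.68, but at that control level a small added share of lymphocytes need not show. A single deviating probe set is argued against for Cd28, whose second probe set rose by 1.65 ± 0.17 (SE, adjusted p = 0.0302). For Klrd1 it stays open, since the array holds 0 further probe sets of that gene among those with 1 symbol. A response of the dendritic cells themselves was not tested for either gene, and for Klrd1 it cannot be told apart from a fault of its single probe set.

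Neutrophil genes split, with Prtn3 12.6-fold higher and Ngp, Ltf, S100a9, Camp and S100a8 lower. The tables argue against a changed share of neutrophils as the source of the rise of Prtn3, since the other 12 markers had a median of -0.75 (95% interval -1.51 to -0.25), and the 11 with every value above the 25th percentile of its array -0.82 (-1.56 to -0.13). More granulocyte progenitors cannot be told apart from a rise in the dendritic cells, since of Mpo and Elane, which such cells make along with Prtn3, Mpo lay under that percentile with SAHA, and Elane alone, with an upper 95% bound of 0.091 on its log2 change, does not decide it. For the 5 falls, fewer neutrophils in the SAHA-treated cultures may be a cause, though selection for CD11c to a stated purity of 95% before treatment should have removed most of them, and since the falls differed by up to 1.06 ± 0.20 (SE) and the dendritic cells' own share of each transcript is unknown, this cannot be told apart from lower expression in the dendritic cells. A response of the dendritic cells and a fault of the 1 probe set of Prtn3 were not tested. The intervals of the neutrophil marker medians likewise run over genes treated as independent, not over replicate arrays.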
